A study of Mus musculus with 8 samples.

How the data were processed

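Total RNA of distal colon from 8 mice was sequenced by the authors with the TruSeq Total RNA kit on a HiSeqX (paired reads of 150 bp). The authors name HISAT2 2.1, SAMtools 1.8, featureCounts and Subread 1.6.2 and the mm10 genome; annotation release, strand setting and the treatment of reads with several matches are not given in the sources used here. Their 2 deposited tables, by gene symbol and by Ensembl ID, hold expected counts without normalization: 18.8% of nonzero values are not whole, at exact equality. The plan had assumed whole counts, so values were rounded to whole numbers. The 2 tables have 55536 lines each and 0 differing values. The 115 symbols on more than 1 line were summed, which left 55418 symbols. All 55450 identifiers found in the reference annotation had the same symbol there, and gene positions come from that annotation.

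Groups came from the labels, with 2 mice in each of 4 groups, and the 5 comparisons were the DSS effect in each genotype, the genotype effect without and after DSS, and the difference of the 2 DSS effects. Genes were filtered with filterByExpr and scaled with TMM factors (0.882 to 1.15), which left 17522 genes out of 30454 with a count. One edgeR quasi-likelihood fit of the 4 group means, with 4 residual degrees of freedom, gave log2 fold changes, two-sided F tests and Benjamini-Hochberg adjusted p, with 0.05 as the threshold over all genes. The SE is the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 17.1% and the prior degrees of freedom 4.28. An exact permutation of 2 against 2 mice cannot go below p = 0.333, so no permutation test is given. The adjusted p measure the spread between mice of a group as pooled over all groups and genes. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

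Gene lists for 26 cell types and pathways were fixed before the data were examined. They were tested with camera in limma on voom values, with a preset correlation of 0.01, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, whose p asks whether a list moves on balance in 1 direction, were run beside it. All 66 camera calls were lost with an estimated correlation, and 32 held with fry. A count of measured members higher or lower uses the threshold over all genes, and each list was also adjusted over the list alone. Where members sat at 0 counts the list median was also computed with bounds: with DSS it went from 6.33 to 5.91 for neutrophil markers in WT mice, from 3.55 to 3.46 in ΔNFκB mice, and from 1.79 to 1.60 for NF-κB response genes in ΔNFκB mice.

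The genes named were chosen by a rule fixed before the data were examined. For each pairwise comparison it takes the 6 largest positive and 6 largest negative log2 fold changes among genes past the threshold with a mean log2 CPM above 1 and groups that do not overlap, without predicted genes or antigen receptor segments. It adds up to 3 members with the smallest p of each list described, and Gm16685, Ppm1d, Mapk14, Rela, Tnf, Il6 and Il1b everywhere. For the difference of responses it takes the 6 smallest p in each direction. The report names the first 2 by p of each list called by camera. All 3 were recomputed under every alternative and enter the counts of named values. Some of the genes so chosen are not reported here. Itgam and Tagln share 68.7% and 67.9% of their exon bases with other genes, so their counts are uncertain.

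A fold against a group at 0 counts is a lower bound from a floor of 3 counts over the group. A group with 1 to 3 counts gives a ratio with its 95% exact counting interval. The floor of 3 counts in 1 library was 0.177 to 0.325 CPM. Intervals and floors cover counting error only, since reads are not independent molecules.

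Sex was read from Y-linked transcripts, as male above a sum of 5 CPM. The alternatives were RLE and upper quartile factors, DESeq2, limma-voom, no count filter, CPM of at least 1 in 2 libraries, the Ensembl table, a replicate block, only the 2 groups compared, immunoglobulin, T cell receptor, mitochondrial and ribosomal RNA genes left out, and each library left out in turn. When a library is left out, its group has 1 mouse, which is assumed to vary like the others. A sex term was added after the data were seen. Groups of 2 allowed neither a test for outlying samples nor other splits of the samples.

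The fit was tested on simulated data with 200 changed genes, so recovery with more calls may differ. At 2-fold, 26.5% to 36.5% were recovered pairwise and 0.5% in the difference. At 4-fold, 79.5% to 83.5% and 71% were recovered, with at most 23 false calls per run. For a simulated list shifted by 1 log2 unit camera gave adjusted p 2.93e-62 (0.00279 with an estimated correlation). It called 1 of 25 other lists.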

Results

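RNA was sequenced from the distal colon of 8 C57BL/6 mice aged 8 to 10 weeks. The mice fell into 4 groups of 2: wild-type (WT) untreated, WT DSS, ΔNFκB untreated and ΔNFκB DSS. ΔNFκB is the name the labels give to a mouse line with an altered NAIL, a long noncoding RNA locus; the labels do not say which bases differ. DSS is dextran sulfate sodium, which damages the colon epithelium when mice drink it; it was in the drinking water at 3% for 4 days, and plain water came back for the last 4 days. Total counts per library ran from 9229861 to 16935961, and 17522 genes were tested. The 2 libraries of a group correlated at 0.974 to 0.981 across genes (Pearson r of log2 CPM, the normalised read count; genes are not independent replicates). Values below are group mean CPM ± SD with n = 2 per group, or log2 fold changes ± SE of the fit.

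Sex, read from Y-linked transcripts, was not balanced across the groups. Both ΔNFκB untreated mice and WT untreated replicate 2 were male, with Y-linked transcripts summing to 219 to 240 CPM, and all 4 DSS mice and WT untreated replicate 1 were female, with at most 0.209 CPM. DSS and sex therefore differed together in ΔNFκB mice and partly in WT mice. Genotype and sex partly did so without DSS, whereas DSS mice were all female. Ribosomal RNA-like transcripts took 3.46% to 6.69% of counts in the DSS libraries and 0.686% to 1.83% in the untreated ones. In a principal component analysis the first component held 52.3% of the variance and separated DSS from untreated libraries, and the second held 24.5% and separated the genotypes after DSS.

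Gm16685 (ENSMUSG00000097804), taken from general knowledge to be the mouse NAIL gene because no label gives its symbol, was counted at 3 and 20 reads in the WT untreated libraries, 57 and 126 in WT DSS, 3 and 4 in ΔNFκB untreated and 55 and 86 in ΔNFκB DSS. It lies at 7612705 to 7690001 on the plus strand of chromosome 3 in mm10 and has 3 exons. All 105 bases of its exon 1 lie inside an exon of Il7 on the other strand, out of 1592 exon bases in all, so reads there cannot be assigned to either gene without strand information. Gm16685 rose with DSS by 3.36 ± 0.63 in WT mice (adjusted p 0.00502) and by 4.64 ± 0.75 in ΔNFκB mice (adjusted p 0.00245). The genotypes differed by -1.51 ± 0.89 without DSS (adjusted p 0.439) and by -0.24 ± 0.52 after DSS (adjusted p 0.782), neither past the test, and the 2 DSS responses differed by 1.27 ± 1.04 (adjusted p 0.408). Each of these 3 values changed sign with 1 library left out, to 0.19, 0.40 and -0.47. Without WT untreated replicate 2 the rise in WT mice was 5.13, and with a sex term, added after the data were seen, the rise in ΔNFκB mice was 7.07. A gene count does not show whether part of the locus was removed.

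**Figure D1:**
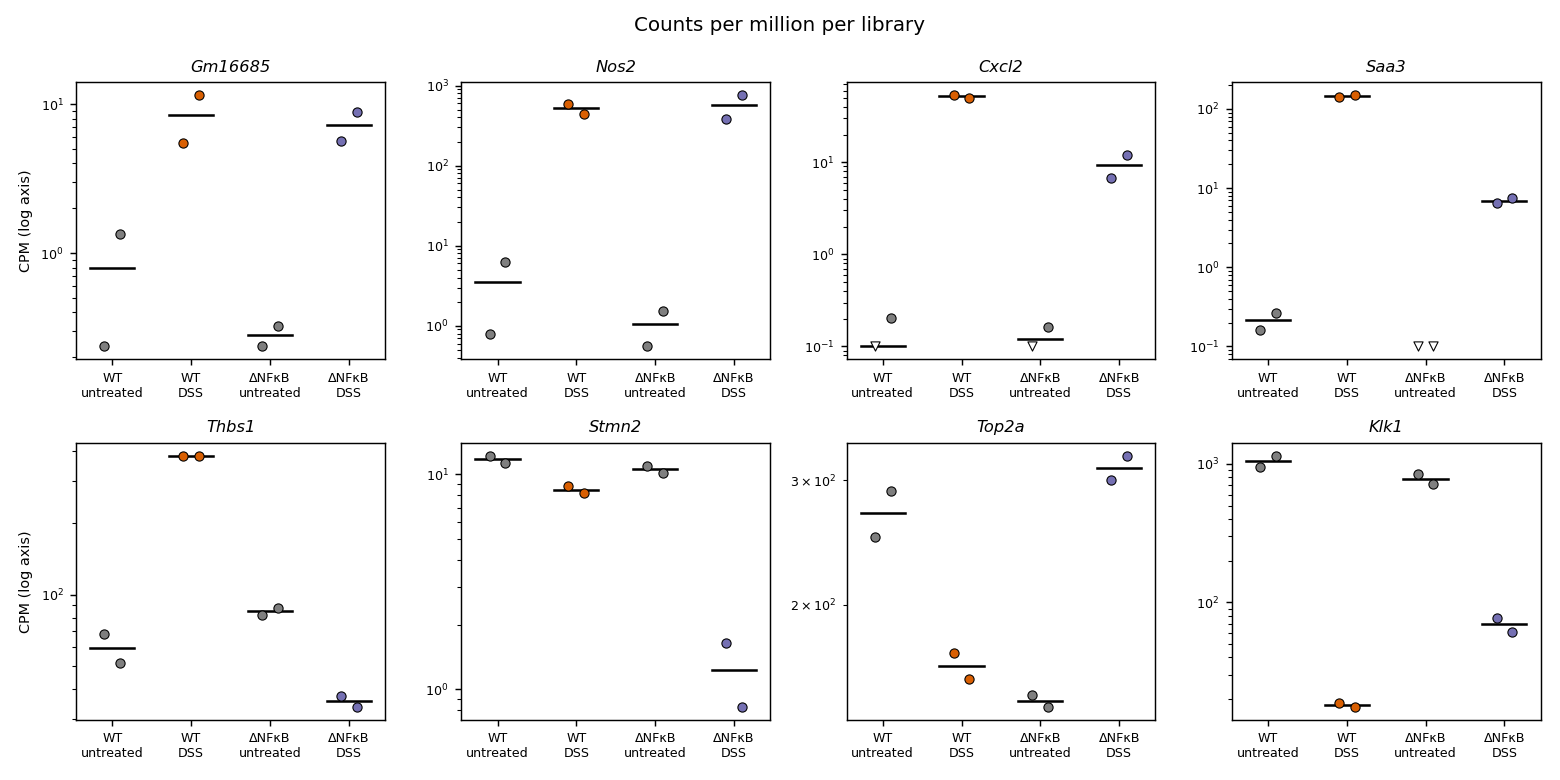
CPM (log axis) of 8 genes in each library, with grey points for untreated, orange for WT DSS and purple for ΔNFκB DSS mice, a bar at each group mean and open triangles, drawn at a fixed low value, for libraries at or near 0 counts. Gm16685 was higher in all 4 DSS libraries than in all 4 untreated ones, and Thbs1 had a mean of 384 CPM in WT DSS and 35.5 CPM in ΔNFκB DSS mice.

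The DSS response of WT mice, with an unaltered locus, set 2 females against 1 female and 1 male. Neutrophil and NF-κB response transcripts rose, and transcripts of goblet cells, absorptive colonocytes and smooth muscle fell. Among neutrophil markers 16 of 17 members were higher and 0 lower (16 and 0 adjusted over the list alone). The neutrophil list had adjusted p 2.82e-09 by camera and adjusted p = 0.263 with an estimated correlation. Il1r2, a decoy receptor for interleukin 1, rose by 5.91 ± 0.27, from 0.441 ± 0.0542 to 27 ± 4.84 CPM, and Mmp9, a gelatinase, by 4.53 ± 0.23 (adjusted p 1.81e-05 and 2.31e-05). Of the NF-κB response genes, 24 of 27 members were higher and 0 lower (26 and 0 adjusted over the list alone). The NF-κB response list had adjusted p 3.25e-09 by camera and adjusted p = 0.263 with an estimated correlation. The neutrophil attractant Cxcl2 was 473-fold (162 to 2298) higher (adjusted p 5.27e-05; ranges after such ratios are 95% counting intervals), and Cxcl5 rose by 6.08 ± 0.48 (adjusted p 0.000168). Tnf rose by 3.49 ± 0.59, Il1b by 5.75 ± 0.69 and Rela by 0.63 ± 0.12 (adjusted p 0.00325, 0.000855 and 0.00542), and Il6 was 206-fold (36.5 to 8199) higher (adjusted p 0.00475). Ppm1d, a phosphatase acting on p38, stood at 0.21 ± 0.17 and Mapk14, which encodes p38α, at 0.18 ± 0.12 (adjusted p 0.351 and 0.276), neither past the test. Tnf rose by 5.37 without WT untreated replicate 2.

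Camera called other lists higher in WT mice. Fry did not call the interferon, fibroblast or T and NK lists. Among interferon response genes 20 of 32 members were higher and 0 lower (23 and 0 adjusted over the list alone). The list had adjusted p 2.32e-07 by camera and adjusted p = 0.532 with an estimated correlation. Gbp5 rose by 4.05 ± 0.32 and Cxcl9 by 5.51 ± 0.53 (adjusted p 0.000167 and 0.000319). For fibroblast and matrix genes 18 of 27 members were higher and 1 lower (20 and 2 adjusted over the list alone). The list had adjusted p 1.94e-06 by camera and adjusted p = 0.532 with an estimated correlation. Thbs1, a matrix glycoprotein, rose by 2.68 ± 0.15 and Col18a1 by 3.10 ± 0.32 (adjusted p 4.06e-05 and 0.000406). In the antimicrobial and acute-phase list 12 of 17 members were higher and 3 lower (12 and 5 adjusted over the list alone). The list had adjusted p 0.00727 by camera and adjusted p = 0.532 with an estimated correlation. Saa3, an acute-phase protein, rose by 9.31 ± 0.22 and Chil1 by 6.18 ± 0.49 (adjusted p 5.41e-06 and 0.00017). The antimicrobial call ended without WT untreated replicate 1 (0.134), in a range of 0.000786 to 0.134. Of the wound-associated epithelial genes 10 of 20 members were higher and 2 lower (11 and 2 adjusted over the list alone). The list had adjusted p 0.00268 by camera and adjusted p = 0.521 with an estimated correlation. Plet1 rose by 7.10 ± 0.61 and Plaur by 3.36 ± 0.37 (adjusted p 0.000204 and 0.000534). Among monocyte and macrophage markers 8 of 21 members were higher and 1 lower (8 and 1 adjusted over the list alone). The list had adjusted p 0.00355 by camera and adjusted p = 0.521 with an estimated correlation. Arg1, arginase, was 119.9-fold (40.6 to 585) higher and Chil3 rose by 8.60 ± 0.77 (adjusted p 0.000228 and 0.000234). Of the T and NK cell markers 6 of 19 members were higher and 0 lower (6 and 0 adjusted over the list alone). The list had adjusted p 0.000111 by camera and adjusted p = 0.532 with an estimated correlation. The granzyme genes Gzmb and Gzma were 72.2-fold (19.5 to 604) and 31.6-fold (8.29 to 268) higher (adjusted p 0.000745 and 0.00204). The fitted log2 rises changed from 6.76 to 10.27 for Arg1 and from 5.96 to 8.95 for Gzmb without WT untreated replicate 1, and from 4.79 to 7.72 for Gzma without WT untreated replicate 2.

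Camera called epithelial and muscle lists lower in WT mice. For goblet cell genes 0 of 18 members were higher and 14 lower (0 and 16 adjusted over the list alone). The goblet cell list had adjusted p 5.52e-10 by camera and adjusted p = 0.263 with an estimated correlation. Klk1 (ENSMUSG00000063903, chromosome 7, 44225360 to 44229618), a kallikrein, fell with log2 fold change -5.86 ± 0.21, from 1049 ± 137 to 18.1 ± 0.812 CPM, and Clca1, a secreted mucus protein, with -5.33 ± 0.29 (adjusted p 6.28e-06 and 3.42e-05). Among absorptive colonocyte genes 0 of 24 members were higher and 17 lower (0 and 19 adjusted over the list alone). The colonocyte list had adjusted p 1.04e-08 by camera and adjusted p = 0.34 with an estimated correlation. The carbonic anhydrases Car2 and Car1 fell with log2 fold change -2.41 ± 0.18 and -2.37 ± 0.20 (adjusted p 0.000145 and 0.000201). Of fatty acid oxidation and ketogenesis genes 0 of 18 members were higher and 14 lower (0 and 16 adjusted over the list alone). The fatty acid list had adjusted p 6.01e-09 by camera and adjusted p = 0.303 with an estimated correlation. Acadm fell with log2 fold change -1.07 ± 0.10 and Acaa2 with -1.19 ± 0.12 (adjusted p 0.000319 and 0.000354). In the mitochondrial respiratory chain list 0 of 20 members were higher and 16 lower (0 and 17 adjusted over the list alone). The mitochondrial list had adjusted p 2.32e-07 by camera and adjusted p = 0.521 with an estimated correlation. Ndufa9 fell with log2 fold change -0.84 ± 0.10 and Uqcrc2 with -1.13 ± 0.14 (adjusted p 0.000932 and 0.000958). For smooth muscle markers 0 of 14 members were higher and 12 lower (0 and 14 adjusted over the list alone). The list had adjusted p 1.79e-07 by camera and adjusted p = 0.521 with an estimated correlation. Myl9 and Myh11, which encode contractile proteins, fell with log2 fold change -2.15 ± 0.24 and -2.0 ± 0.25 (adjusted p 0.000642 and 0.000928). Among crypt base stem cell genes 1 of 16 members were higher and 7 lower (1 and 9 adjusted over the list alone). The crypt base list had adjusted p 0.00784 by camera and adjusted p = 0.521 with an estimated correlation. The stem cell receptor Lgr5 was 76.5-fold (25.9 to 373) lower and Myb fell with log2 fold change -1.24 ± 0.18 (adjusted p 0.00099 and 0.00168). Without WT DSS replicate 1 the fitted value of Lgr5 was -10.04 in place of -6.19.

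The largest rises in WT mice, in genes at 0 counts without DSS, were at least 347-fold for Retnlg, at least 242-fold for Prss22, at least 237-fold for Mmp8, at least 207-fold for Myot and at least 198-fold for Ngp (adjusted p 0.000105, 0.000233, 0.000319, 0.000615 and 0.0067). S100a8, a neutrophil calcium-binding protein, was 2593-fold (465 to 102471) higher (adjusted p 0.000317). Among the largest falls were Mptx1 at -10.69 ± 0.50 (adjusted p 1.81e-05), beside Otc, Retnla and Smpx, which were 157-fold (27.9 to 6248), 119-fold (21.1 to 4748) and 93.1-fold (25.5 to 773) lower (adjusted p 0.000232, 0.000958 and 6.04e-05). In all, 6315 genes changed (4305 with a sex term), 3022 up and 3293 down, 3100 of them at least 2-fold. The number was 4177 without WT untreated replicate 2, 3512 without WT DSS replicate 1 and 3298 without WT DSS replicate 2. All 57 called values of named genes stayed past the test with each library left out in turn. The test was not passed by the cell cycle list (1 of 24 measured members higher and 10 lower, adjusted p 0.0637), adipocyte markers (0.0643), enteroendocrine genes (0.0688), endothelial markers (0.238), B and plasma cell markers (0.319), stratified squamous markers (0.319), the p38 list (0.369), red blood cell markers (0.528), skeletal muscle markers (0.677), nerve and glia markers (0.677), sex-linked transcripts (0.764) or immediate early genes (0.779).

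**Figure D2:**
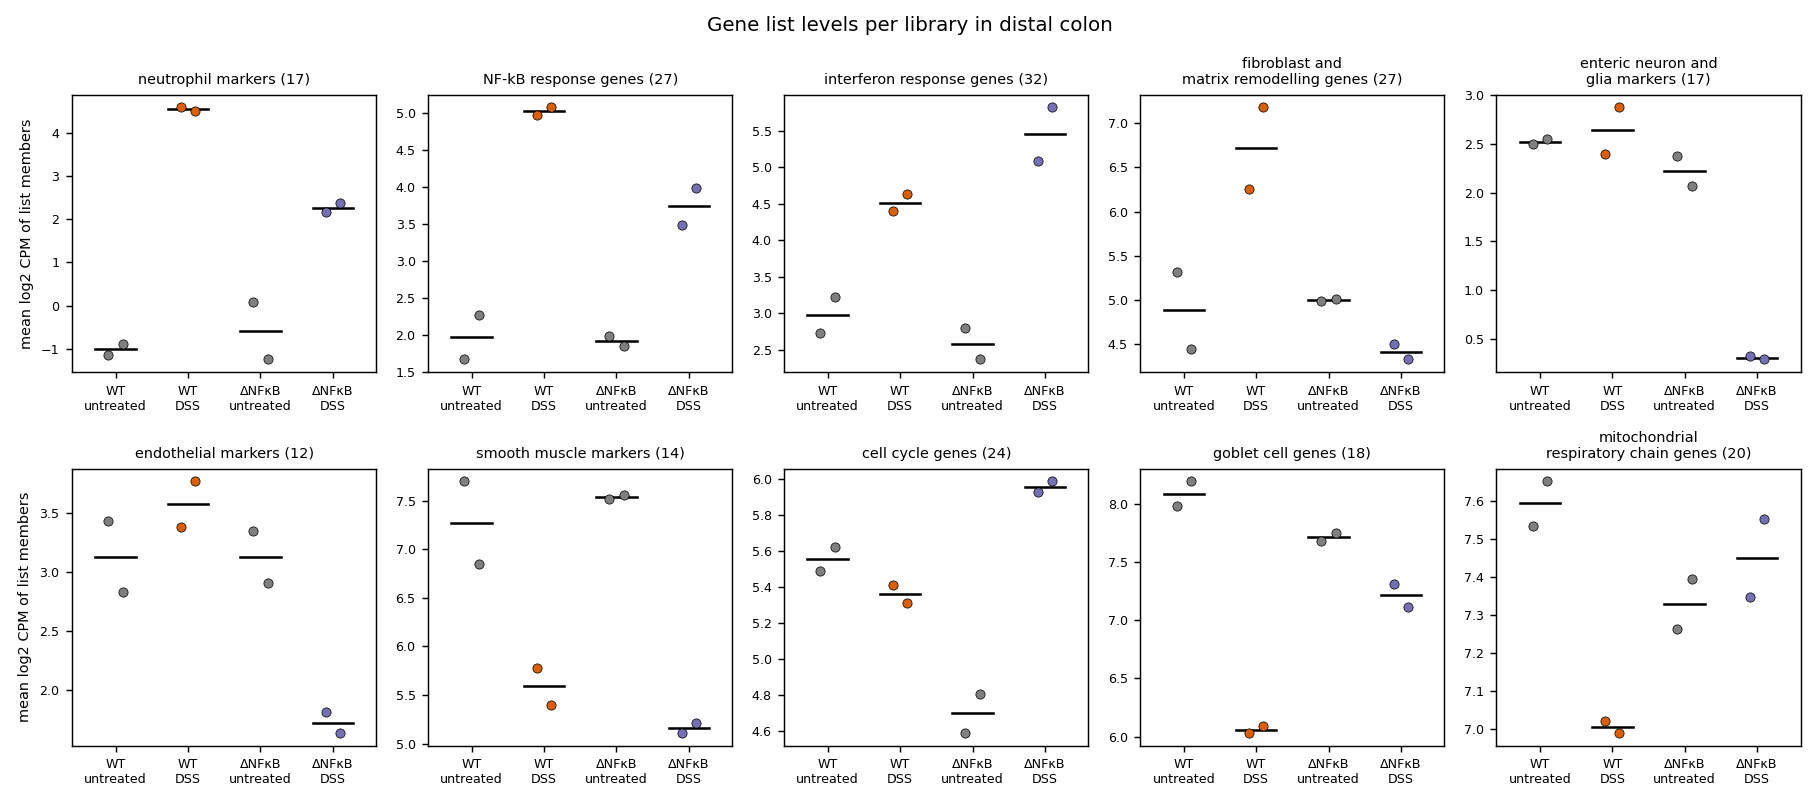
Mean log2 CPM of the members of 10 gene lists in each library, with a bar at each group mean and the number of measured members in brackets. Nerve and glia markers stood at 0.287 and 0.326 in the ΔNFκB DSS libraries and between 2.07 and 2.87 in the other 6 libraries.

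The DSS response of ΔNFκB mice, with the altered locus, had the limit that both untreated mice were male and both DSS mice female. Interferon response, cell cycle, neutrophil and antimicrobial genes rose, and smooth muscle, nerve and vessel markers fell. The T and NK, endothelial, fibroblast and crypt base lists below were called by camera but not by fry (fry adjusted p 0.318, 0.0534, 0.247 and 0.0542). Among interferon response genes 31 of 32 members were higher and 0 lower (32 and 0 adjusted over the list alone). The interferon list had adjusted p 1.97e-16 by camera and adjusted p = 0.421 with an estimated correlation. Tap1 rose by 3.16 ± 0.25, from 16.7 ± 4.96 to 149 ± 37.8 CPM, and Psmb9, a proteasome subunit, by 2.81 ± 0.22 (adjusted p 0.000159 and 0.000165). For cell cycle genes 23 of 24 members were higher and 0 lower (23 and 0 adjusted over the list alone). The cell cycle list had adjusted p 1.06e-14 by camera and adjusted p = 0.345 with an estimated correlation. Ube2c and Birc5, both active in mitosis, rose by 2.04 ± 0.16 and 1.66 ± 0.15 (adjusted p 0.000173 and 0.000288). Among neutrophil markers 15 of 17 members were higher and 0 lower (15 and 0 adjusted over the list alone). The neutrophil list had adjusted p 1.10e-05 by camera and adjusted p = 0.345 with an estimated correlation. Il1r2 rose by 3.62 ± 0.34 and Retnlg was 77-fold (20.9 to 643) higher (adjusted p 0.000293 and 0.000528). In the antimicrobial and acute-phase list 12 of 17 members were higher and 0 lower (13 and 1 adjusted over the list alone). The antimicrobial list had adjusted p 3.39e-05 by camera and adjusted p = 0.421 with an estimated correlation. Saa3 was at least 57.7-fold higher and Ido1, which degrades tryptophan, rose by 8.18 ± 0.64 (adjusted p 7.28e-05 and 0.000165). Of the NF-κB response genes 14 of 27 members were higher and 1 lower (14 and 1 adjusted over the list alone). The NF-κB response list had adjusted p 0.000908 by camera and adjusted p = 0.421 with an estimated correlation. Cxcl5 rose by 6.49 ± 0.51 and Nos2 by 9.09 ± 0.83 (adjusted p 0.000159 and 0.000271). Among T and NK cell markers 4 of 19 members were higher and 0 lower (2 and 0 adjusted over the list alone). The list had adjusted p 0.0209 by camera and adjusted p = 0.707 with an estimated correlation. Gzmb rose by 5.05 ± 0.63 and Gzma was 20.5-fold (6.62 to 103) higher (adjusted p 0.000859 and 0.0023). The T and NK list was no longer called with a replicate block (0.0685), and without ΔNFκB untreated replicate 2 its direction turned (0.792), in a range of 1.53e-06 to 0.792.

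Other groups fell in ΔNFκB mice. For smooth muscle markers 0 of 14 members were higher and 14 lower (0 and 14 adjusted over the list alone). The list had adjusted p 8.39e-10 by camera and adjusted p = 0.421 with an estimated correlation. Myl9 fell with log2 fold change -2.92 ± 0.25 and Myh11 with -2.75 ± 0.25 (adjusted p 0.000216 and 0.000283). Among enteric neuron and glia markers 0 of 17 members were higher and 13 lower (0 and 14 adjusted over the list alone). The list had adjusted p 1.68e-05 by camera and adjusted p = 0.345 with an estimated correlation. Stmn2 (ENSMUSG00000027500), a neuronal microtubule protein, fell with log2 fold change -3.09 ± 0.29, from 10.6 ± 0.562 to 1.23 ± 0.576 CPM, and Uchl1 with -3.11 ± 0.30 (adjusted p 0.000288 and 0.000315). Of endothelial markers 0 of 12 members were higher and 7 lower (0 and 9 adjusted over the list alone). The list had adjusted p 0.0010 by camera and adjusted p = 0.532 with an estimated correlation. The receptor genes Tek and Lyve1 fell with log2 fold change -2.72 ± 0.28 and -2.40 ± 0.27 (adjusted p 0.000412 and 0.00056). In the fibroblast list 0 of 27 members were higher and 9 lower (0 and 9 adjusted over the list alone). The list had adjusted p 0.00711 by camera and adjusted p = 0.707 with an estimated correlation. Thbs1 fell with log2 fold change -1.26 ± 0.15 and Postn with -2.21 ± 0.35 (adjusted p 0.000672 and 0.00225). Among absorptive colonocyte genes 2 of 24 members were higher and 11 lower (3 and 12 adjusted over the list alone). The list had adjusted p 0.000908 by camera and adjusted p = 0.532 with an estimated correlation. Car1 fell with log2 fold change -3.89 ± 0.22 and Slc16a1 with -1.31 ± 0.11 (adjusted p 6.11e-05 and 0.000194). The colonocyte call ended with a sex term (0.429), in a range of 4.16e-05 to 0.429. For fatty acid oxidation and ketogenesis genes 2 of 18 members were higher and 11 lower (2 and 12 adjusted over the list alone). The list had adjusted p 0.000639 by camera and adjusted p = 0.503 with an estimated correlation. Acaa2 fell with log2 fold change -1.62 ± 0.12 (adjusted p 0.000147). Among crypt base genes 1 of 16 members were higher and 6 lower (1 and 6 adjusted over the list alone). The list had adjusted p 0.0304 by camera and adjusted p = 0.532 with an estimated correlation. Sox9 fell with log2 fold change -1.52 ± 0.22, whereas Ephb2 rose by 0.92 ± 0.16 (adjusted p 0.00147 and 0.00334). The crypt base call ended without ΔNFκB DSS replicate 2 (0.0904), in a range of 0.00907 to 0.0904. Goblet cell genes had 4 of 18 measured members higher and 7 lower and did not pass the list test (adjusted p 0.158). Neither did the mitochondrial list (4 of 20 higher, 0 lower, adjusted p 0.158) or the p38 list (2 of 23 higher, 3 lower, adjusted p 0.993).

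Sex-linked transcripts were among the largest changes in ΔNFκB mice, whose DSS and untreated groups differed in sex. Xist, expressed from the inactive X chromosome of females, was higher by 9.82 ± 2.47 (adjusted p 0.0165), and the Y-linked genes Uty, Ddx3y, Kdm5d and Eif2s3y were at least 428-fold, at least 415-fold, at least 371-fold and at least 339.6-fold lower (adjusted p 0.0288, 0.0287, 0.0423 and 0.0413). The other largest rises were Retnlb, a goblet cell protein, 951-fold (325 to 4615) higher, Sprr2h, 856-fold (153 to 33849) higher, Saa3 and Nos2 as above, and Clca4b at 8.65 ± 0.81 (adjusted p 0.000206, 0.000216 and 0.000288). Inmt was at least 32.5-fold lower and Cyp2c69 at least 19.7-fold lower (adjusted p 0.00141 and 0.00403). Tnf rose by 4.24 ± 0.63, Il1b by 4.25 ± 0.74 and Rela by 0.49 ± 0.12 (adjusted p 0.00171, 0.00339 and 0.0142). Il6, at 0 counts in both untreated libraries, was at least 2.14-fold higher in the DSS mice (adjusted p 0.216), and Ppm1d stood at -0.23 ± 0.17 and Mapk14 at 0.18 ± 0.12 (adjusted p 0.336 and 0.289), none of them past the test.

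Across ΔNFκB mice 6199 genes changed with DSS, 2832 up and 3367 down, 3298 of them at least 2-fold. The number was 4036 without ΔNFκB untreated replicate 1, 3816 without ΔNFκB DSS replicate 1, 3373 without ΔNFκB DSS replicate 2 and 3343 with a sex term. That term rests on the 2 WT untreated mice, the only group with both sexes. It took the members higher from 15 to 4 for neutrophil, 31 to 26 for interferon, 14 to 11 for NF-κB and 4 to 1 for T and NK lists. Those lower went from 13 to 8 for nerve and glia, 11 to 8 for colonocyte, 11 to 5 for fatty acid and 9 to 16 for fibroblast lists. Of 52 called values of named genes 8 lost the call without at least 1 library. Xist lost it without ΔNFκB untreated replicate 1 (0.0961) and ΔNFκB untreated replicate 2 (0.0879) and with limma-voom (0.198), in a range of 5.52e-07 to 0.757. Uty lost it without ΔNFκB untreated replicate 1 (0.0674), ΔNFκB untreated replicate 2 (0.0619), ΔNFκB DSS replicate 1 (0.109) and ΔNFκB DSS replicate 2 (0.119) and with limma-voom (0.199), in a range of 9.65e-08 to 1. Ddx3y lost its call without ΔNFκB untreated replicate 1 (0.0694), ΔNFκB untreated replicate 2 (0.0593), ΔNFκB DSS replicate 1 (0.109) and ΔNFκB DSS replicate 2 (0.119) and with limma-voom (0.194), in a range of 4.62e-08 to 1. The sex term also ended these 3 calls, with signs turned (-0.17, 0.067 and 0.039). Kdm5d lost its call without ΔNFκB untreated replicate 1 (0.092), ΔNFκB untreated replicate 2 (0.0904), ΔNFκB DSS replicate 1 (0.138) and ΔNFκB DSS replicate 2 (0.15) and with limma-voom (0.18) and a sex term (1), in a range of 1.70e-06 to 1. Eif2s3y lost its call without ΔNFκB untreated replicate 1 (0.0946), ΔNFκB untreated replicate 2 (0.0844), ΔNFκB DSS replicate 1 (0.135) and ΔNFκB DSS replicate 2 (0.147) and with limma-voom (0.211) and a sex term (0.341), in a range of 5.49e-05 to 0.341. Rela lost it without ΔNFκB untreated replicate 1 (0.0687) and ΔNFκB DSS replicate 1 (0.0868) and with a sex term (0.0837), in a range of 0.0104 to 0.0868. The sex term alone ended the calls of Sprr2h (adjusted p 0.138, in a range of 4.24e-10 to 0.138), Ephb2 (0.14, in a range of 1.86e-05 to 0.14), Retnlg (1, in a range of 2.67e-08 to 1) and Gzmb (0.826, in a range of 3.40e-07 to 0.826). With that term the fitted changes were 10.46 for Cxcl2, 8.00 for Gzma, 6.81 for Tnf and -3.51 for Postn. Without ΔNFκB untreated replicate 1 Retnlg stood at 9.14 in place of 6.09.

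Untreated genotypes were compared with sex partly matched. Cell cycle genes were lower in ΔNFκB mice as a list. Of cell cycle genes 0 of 24 members were higher and 10 lower (0 and 21 adjusted over the list alone). The list had adjusted p 2.07e-25 by camera and adjusted p = 0.326 with an estimated correlation. Ccnb1, cyclin B1, was lower with log2 fold change -1.48 ± 0.16, at 53.5 ± 1.62 CPM in WT and 19.2 ± 3.93 CPM in ΔNFκB mice, and Cenpf, a kinetochore protein, with -1.15 ± 0.13 (adjusted p 0.0298 and 0.0298). The other largest falls were Pla2g5 (-1.47 ± 0.22), Cdc25c (-1.46 ± 0.19), Cdca3 (-1.29 ± 0.15), Shcbp1 (-1.27 ± 0.18) and Nox1 (-1.24 ± 0.18; adjusted p 0.0412, 0.0298, 0.0298, 0.0383 and 0.0412). The largest rises were Nr4a1 (1.73 ± 0.25), Abcg5 (1.55 ± 0.23), Adamts15 (1.0 ± 0.12), Mroh3 (1.0 ± 0.15), Safb2 (0.78 ± 0.10) and Tmem64 (0.72 ± 0.11; adjusted p 0.0383, 0.0424, 0.0298, 0.0412, 0.0298 and 0.0412). In all 68 genes passed, 7 higher and 61 lower, and 2832 had an unadjusted p under 0.05. The number was 200 without WT untreated replicate 1, 5 without WT untreated replicate 2, 27 without ΔNFκB untreated replicate 2 and 0 without WT DSS replicate 1, WT DSS replicate 2, ΔNFκB untreated replicate 1, ΔNFκB DSS replicate 1 or ΔNFκB DSS replicate 2. It was 264 with DESeq2, 330 without a count filter, 176 with a sex term, and 0 with a replicate block or with only the 2 groups compared. Each of the 14 called values of named genes lost its call under at least 6 of the left-out libraries, reaching adjusted p 0.231 for Ccnb1 (1.59e-08 to 0.231 over the alternatives) and 0.28 for Mroh3 (0.00512 to 0.28).

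Beyond the cell cycle list, camera but not fry called 9 lists in untreated mice, with at most 1 member past over all genes. Mitochondrial respiratory chain genes were lower as a list with 1 of 20 members past the test adjusted over the list alone (adjusted p 1.07e-06 by camera and adjusted p = 0.632 with an estimated correlation), and goblet cell genes with 6 of 18 (adjusted p 2.20e-05 by camera and adjusted p = 0.632 with an estimated correlation). Ndufa9 stood at -0.46 ± 0.10 and Ndufa10 at -0.42 ± 0.12 (adjusted p 0.128 and 0.192), and Agr2 at -0.81 ± 0.15 and Spink4 at -0.95 ± 0.20 (adjusted p 0.0905 and 0.12). Antimicrobial genes had 1 member lower over all genes, Nox1, and 5 of 17 over the list alone (adjusted p 0.00262 by camera and adjusted p = 0.632 with an estimated correlation); Wfdc18 stood at -1.80 ± 0.44 (adjusted p 0.15). Adipocyte markers had 6 of 8 lower over the list alone (adjusted p 0.00694 by camera and adjusted p = 0.632 with an estimated correlation); Adipoq stood at -4.12 ± 0.86 and Cfd at -3.87 ± 0.87 (adjusted p 0.123 and 0.132), with Cfd at 38 ± 40.7 CPM in WT and 2.6 ± 0.000338 CPM in ΔNFκB mice. Fatty acid oxidation genes had 1 of 18 lower over the list alone (adjusted p 0.00423 by camera and adjusted p = 0.632 with an estimated correlation), enteroendocrine genes 2 of 12 (adjusted p 0.0156 by camera and adjusted p = 0.632 with an estimated correlation), nerve and glia markers 1 of 17 (adjusted p 0.0458 by camera and adjusted p = 0.807 with an estimated correlation) and interferon response genes 0 of 32 (adjusted p 0.0168 by camera and adjusted p = 0.907 with an estimated correlation). Smooth muscle markers were higher as a list with 0 of 14 members past either test (adjusted p 0.0458 by camera and adjusted p = 0.907 with an estimated correlation). Decr1 stood at -0.59 ± 0.13, Hadha at -0.40 ± 0.12, Gcg at -0.89 ± 0.21, Insl5 at -1.30 ± 0.35, Nos1 at -0.94 ± 0.20, Isg15 at -1.96 ± 0.48, Zbp1 at -1.64 ± 0.40, Hspb6 at 0.45 ± 0.23 and Lmod1 at 0.37 ± 0.19, with adjusted p from 0.12 to 0.38, none past the test.

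Several of these list calls ended with 1 library left out. The adipocyte call ended without ΔNFκB untreated replicate 2 (0.0765), in a range of 2.78e-07 to 0.0765, and with a sex term 4 members were lower. The nerve and glia call ended without WT untreated replicate 1 (0.0632), WT untreated replicate 2 (0.123) and ΔNFκB untreated replicate 2 (0.376), in a range of 0.0137 to 0.376. The enteroendocrine call ended without WT untreated replicate 2 (0.0926) and ΔNFκB untreated replicate 2 (0.0574), in a range of 0.00645 to 0.0926. The antimicrobial call ended without WT untreated replicate 2 (0.296), in a range of 5.36e-07 to 0.296. The interferon call ended without WT untreated replicate 2 (0.536) and ΔNFκB untreated replicate 2 (0.504), in a range of 0.000872 to 0.536. The smooth muscle call ended without ΔNFκB untreated replicate 2 (0.188), in a range of 3.44e-10 to 0.188, and without WT untreated replicate 2 its direction turned (0.0231). The p38 list did not pass (adjusted p 0.133 by camera and adjusted p = 0.632 with an estimated correlation), and Ppm1d stood at 0.30 ± 0.17, Mapk14 at 0.20 ± 0.12, Rela at 0.10 ± 0.12, Tnf at -0.56 ± 0.75 and Il1b at -0.56 ± 0.92 (adjusted p 0.416, 0.459, 0.729, 0.757 and 0.803). Il6 had 0 and 1 counts in WT and 0 in both ΔNFκB untreated libraries, too few for a fold. ΔNFκB untreated replicate 1 held 4394 counts of Tgm4 and 1363 of Pbsn, transcripts of male accessory glands, WT untreated replicate 2 held 23 and 16, and other libraries at most 1.

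The genotype comparison after DSS asks how treated colon differed between the lines. By camera and fry, fibroblast, nerve, vessel and neutrophil lists were lower in ΔNFκB mice and goblet cell, cell cycle and mitochondrial lists higher. Other list calls were by camera only. Among fibroblast and matrix genes 0 of 27 members were higher and 23 lower (0 and 26 adjusted over the list alone). The fibroblast list had adjusted p 5.47e-14 by camera and adjusted p = 0.432 with an estimated correlation. Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133) was lower with log2 fold change -3.43 ± 0.16, at 384 ± 0.47 CPM in WT and 35.5 ± 2.76 CPM in ΔNFκB mice, and Col18a1 with -2.94 ± 0.32 (adjusted p 8.90e-05 and 0.00251). For nerve and glia markers 0 of 17 members were higher and 15 lower (0 and 16 adjusted over the list alone). The list had adjusted p 1.08e-10 by camera and adjusted p = 0.263 with an estimated correlation. Nos1 was lower with log2 fold change -2.82 ± 0.23 and Uchl1 with -2.91 ± 0.30 (adjusted p 0.00115 and 0.00218). Among endothelial markers 0 of 12 members were higher and 10 lower (0 and 12 adjusted over the list alone). The list had adjusted p 1.81e-07 by camera and adjusted p = 0.432 with an estimated correlation. Tek and Cdh5 were lower with log2 fold change -2.17 ± 0.28 and -2.99 ± 0.41 (adjusted p 0.00332 and 0.0038). Of neutrophil markers 0 of 17 members were higher and 14 lower (0 and 16 adjusted over the list alone). The neutrophil list had adjusted p 4.68e-11 by camera and adjusted p = 0.262 with an estimated correlation. Il1r2 was lower with log2 fold change -3.13 ± 0.22 and Mmp9 with -2.55 ± 0.20 (adjusted p 0.000796 and 0.00108). In the NF-κB response list 0 of 27 members were higher and 14 lower (1 and 15 adjusted over the list alone). The list had adjusted p 0.000124 by camera and adjusted p = 0.432 with an estimated correlation. Ptgs2, an inducible cyclooxygenase, was lower with log2 fold change -3.47 ± 0.41 and Cxcl2 with -2.48 ± 0.31 (adjusted p 0.00276 and 0.00318). Among monocyte and macrophage markers 0 of 21 members were higher and 7 lower (0 and 8 adjusted over the list alone). The macrophage list had adjusted p 0.000394 by camera and adjusted p = 0.444 with an estimated correlation. Arg1 was lower with log2 fold change -4.39 ± 0.49 and Itgam with -2.17 ± 0.36 (adjusted p 0.0026 and 0.00668). The count of Itgam is uncertain, since 68.7% of its exon bases lie in exons of other genes. Itgam lost its call without WT DSS replicate 2 (0.0513), in a range of 7.75e-05 to 0.0513. Of wound-associated genes 0 of 20 members were higher and 6 lower (0 and 8 adjusted over the list alone). The wound-associated list had adjusted p 0.00719 by camera and adjusted p = 0.514 with an estimated correlation. Il33 was lower with log2 fold change -2.09 ± 0.27 and Il11 with -4.81 ± 0.73 (adjusted p 0.00332 and 0.00533). Il11 lost its call without ΔNFκB DSS replicate 2 (0.0579) and with limma-voom (0.0517), in a range of 1.22e-10 to 0.0579.

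Another 3 lists were lower in ΔNFκB mice after DSS with fewer members past the test. For smooth muscle markers 0 of 14 members were higher and 2 lower (0 and 2 adjusted over the list alone). The smooth muscle list had adjusted p 0.0234 by camera and adjusted p = 0.728 with an estimated correlation. Lmod1 was lower with log2 fold change -1.08 ± 0.21 and Kcnmb1 with -1.01 ± 0.28 (adjusted p 0.0132 and 0.0385). The smooth muscle call ended without WT DSS replicate 1 (0.224) and ΔNFκB DSS replicate 1 (0.0582), in a range of 0.00107 to 0.224. With a sex term 5 members were lower. Lmod1 lost its call without WT DSS replicate 1 (0.0664), ΔNFκB DSS replicate 1 (0.0799) and ΔNFκB DSS replicate 2 (0.052), in a range of 0.000675 to 0.0799. Kcnmb1 lost its call without WT DSS replicate 1 (0.0899), WT DSS replicate 2 (0.175), ΔNFκB untreated replicate 1 (0.0525), ΔNFκB untreated replicate 2 (0.053), ΔNFκB DSS replicate 1 (0.174) and ΔNFκB DSS replicate 2 (0.11) and with limma-voom (0.0742) and a replicate block (0.0513), in a range of 0.0121 to 0.175. Of red blood cell markers 0 of 4 members were higher and 3 lower (0 and 4 adjusted over the list alone). The red blood cell list had adjusted p 0.0385 by camera and adjusted p = 0.556 with an estimated correlation. The globin genes Hba-a1 and Hbb-bs were lower with log2 fold change -1.90 ± 0.46 and -1.71 ± 0.42 (adjusted p 0.0255 and 0.0261). The red blood cell call ended without WT untreated replicate 1 (0.0754), WT untreated replicate 2 (0.0753), WT DSS replicate 2 (0.124) and ΔNFκB DSS replicate 1 (0.077) and with a sex term (0.0575), in a range of 0.00303 to 0.124. Hba-a1 lost its call without WT DSS replicate 2 (0.138), ΔNFκB DSS replicate 1 (0.0997) and ΔNFκB DSS replicate 2 (0.155) and with limma-voom (0.0633), in a range of 0.00274 to 0.155. Hbb-bs lost its call without WT DSS replicate 2 (0.161), ΔNFκB DSS replicate 1 (0.13) and ΔNFκB DSS replicate 2 (0.108) and with limma-voom (0.0595), in a range of 0.00254 to 0.161. B and plasma cell markers were lower as a list with 0 of 18 members past either test (adjusted p 0.00442 by camera and adjusted p = 0.717 with an estimated correlation); Pou2af1 stood at -1.93 ± 0.97 and Blk at -1.73 ± 1.09 (adjusted p 0.189 and 0.288). The B cell call ended without ΔNFκB DSS replicate 2 (0.78), in a range of 0.000871 to 0.78, and mean log2 CPM of these markers was 3.99 in ΔNFκB DSS replicate 1 and -0.32 in replicate 2.

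Goblet cell genes were higher in ΔNFκB mice after DSS: 15 of 18 members were higher and 0 lower (15 and 0 adjusted over the list alone). The goblet cell list had adjusted p 1.51e-11 by camera and adjusted p = 0.262 with an estimated correlation. Klk1 was higher by 1.94 ± 0.18, at 18.1 ± 0.812 CPM in WT and 69.2 ± 11.6 CPM in ΔNFκB mice, and Gcnt3 by 1.49 ± 0.16 (adjusted p 0.00154 and 0.0025). For cell cycle genes 14 of 24 members were higher and 0 lower (20 and 0 adjusted over the list alone). The cell cycle list had adjusted p 2.51e-10 by camera and adjusted p = 0.376 with an estimated correlation. Top2a and Bub1 were higher by 0.93 ± 0.12 and 0.99 ± 0.14 (adjusted p 0.0033 and 0.00456). Among interferon response genes 13 of 32 members were higher and 1 lower (18 and 1 adjusted over the list alone). The interferon list had adjusted p 3.50e-08 by camera and adjusted p = 0.514 with an estimated correlation. Psmb9 was higher by 1.26 ± 0.21 and Oasl2 by 1.84 ± 0.30 (adjusted p 0.00668 and 0.00681). Of mitochondrial respiratory chain genes 14 of 20 members were higher and 0 lower (17 and 0 adjusted over the list alone). The mitochondrial list had adjusted p 3.68e-08 by camera and adjusted p = 0.444 with an estimated correlation. Cyc1 was higher by 0.60 ± 0.11 and Cox5a by 0.54 ± 0.11 (adjusted p 0.00871 and 0.0142). Among absorptive colonocyte genes 7 of 24 members were higher and 2 lower (8 and 2 adjusted over the list alone). The colonocyte list had adjusted p 0.00273 by camera and adjusted p = 0.526 with an estimated correlation. Car1 was lower with log2 fold change -2.02 ± 0.20 and the water channel gene Aqp8 higher by 4.40 ± 0.57 (adjusted p 0.0019 and 0.00332). The call of Bub1 ended without ΔNFκB DSS replicate 2 (0.0508), in a range of 0.000606 to 0.0508. Psmb9 lost its call without ΔNFκB DSS replicate 2 (0.0714), in a range of 5.35e-05 to 0.0714. Oasl2 lost its call without WT DSS replicate 2 (0.0561), in a range of 6.65e-09 to 0.0561. Cyc1 lost its call without WT DSS replicate 2 (0.0778) and ΔNFκB DSS replicate 2 (0.0906), in a range of 0.00139 to 0.0906. Cox5a lost its call without WT DSS replicate 1 (0.0749), WT DSS replicate 2 (0.081) and ΔNFκB DSS replicate 2 (0.143), in a range of 0.00556 to 0.143.

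The genes furthest above WT after DSS were Mptx1 at 4.89 ± 0.54, Cma1 at 3.51 ± 0.40, Abo at 3.40 ± 0.37 and Alox15 at 3.39 ± 0.60 (adjusted p 0.0026, 0.00267, 0.00257 and 0.00865), beside Aqp8 as above and Lgr5, 26.6-fold (8.75 to 132) higher (adjusted p 0.00961). Those furthest below were Dio2 at -8.04 ± 1.16, Mmp3 at -5.74 ± 0.91, Krt90 at -5.51 ± 0.53, Ngp at -5.51 ± 1.28, Pi15 at -5.50 ± 0.91 and Marco at -5.46 ± 1.6 (adjusted p 0.00456, 0.00603, 0.00177, 0.0255, 0.00696 and 0.0461). Mmp3, Dio2, Pi15 and Marco had an SD across the WT DSS mice about as large as their mean (93.9 ± 95.3, 83.9 ± 90.4, 37.6 ± 38.4 and 14 ± 14.5 CPM). The call of Lgr5 ended without WT DSS replicate 2 (0.0596) and with limma-voom (0.0624), in a range of 3.35e-05 to 0.0624, and without WT DSS replicate 1 its fitted value was 8.48 in place of 4.63. The call of Alox15 ended without WT DSS replicate 1 (0.0512) and ΔNFκB DSS replicate 2 (0.0748), in a range of 0.000208 to 0.0748. Dio2 lost its call without ΔNFκB DSS replicate 2 (0.0591) and with limma-voom (0.142), in a range of 6.20e-10 to 0.142. Mmp3 lost its call without ΔNFκB DSS replicate 2 (0.0743) and with limma-voom (0.0624), in a range of 9.75e-07 to 0.0743. Pi15 lost its call without ΔNFκB DSS replicate 1 (0.0512) and ΔNFκB DSS replicate 2 (0.0674) and with limma-voom (0.0969), in a range of 8.59e-07 to 0.0969. Ngp lost its call without WT DSS replicate 1 (0.0707), WT DSS replicate 2 (0.113), ΔNFκB DSS replicate 1 (0.124) and ΔNFκB DSS replicate 2 (0.143) and with DESeq2 (0.133), in a range of 8.01e-05 to 0.143. Marco lost its call without WT untreated replicate 1 (0.0534), WT untreated replicate 2 (0.0531), WT DSS replicate 2 (0.257), ΔNFκB DSS replicate 1 (0.158) and ΔNFκB DSS replicate 2 (0.24) and with DESeq2 (0.0972), limma-voom (0.191) and a replicate block (0.0647), in a range of 0.000976 to 0.257. Without WT DSS replicate 2 the change was -3.64 for Pi15, -3.56 for Marco and -1.01 for Hbb-bs.

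Among genes named in every comparison, Il6 was lower in ΔNFκB mice after DSS with log2 fold change -4.79 ± 1.01 and Il1b with -2.07 ± 0.55 (adjusted p 0.0193 and 0.0329). Il6 lost its call without WT DSS replicate 2 (0.106), ΔNFκB DSS replicate 1 (0.0995) and ΔNFκB DSS replicate 2 (0.109) and with limma-voom (0.0839), in a range of 0.000115 to 0.109. Il1b lost its call without WT DSS replicate 1 (0.216), ΔNFκB DSS replicate 1 (0.16) and ΔNFκB DSS replicate 2 (0.105) and with DESeq2 (0.0743) and a replicate block (0.0544), in a range of 0.000419 to 0.216. Without WT DSS replicate 2 the change of Il6 was -3.17, and without WT DSS replicate 1 that of Il1b was -1.02. Tnf stood at 0.18 ± 0.48, Rela at -0.04 ± 0.12, Ppm1d at -0.14 ± 0.17 and Mapk14 at 0.20 ± 0.12 (adjusted p 0.814, 0.847, 0.602 and 0.287), and the p38 list, with 1 of 23 members higher and 2 lower, did not pass (adjusted p 0.849). In all 3499 genes differed, 1457 higher and 2042 lower in ΔNFκB mice, 2023 of them at least 2-fold. The number was 1770 without WT DSS replicate 1, 890 without WT DSS replicate 2, 1568 without ΔNFκB DSS replicate 1 and 484 without ΔNFκB DSS replicate 2. Of 54 called values of named genes, 26 kept their call with each library left out in turn and 28 lost it without at least 1.

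The difference of the 2 DSS responses, a test of genotype by treatment, includes the untreated mice with sex partly matched. By camera and fry, responses of cell cycle, goblet cell and mitochondrial lists were higher in ΔNFκB mice and that of nerve markers lower. Other list calls were by camera only. For cell cycle genes 23 of 24 members were higher and 0 lower (24 and 0 adjusted over the list alone). The list had adjusted p 3.85e-18 by camera and adjusted p = 0.286 with an estimated correlation. Top2a fell from 269 ± 28.2 to 164 ± 9.88 CPM in WT mice and rose from 146 ± 4.16 to 312 ± 17.7 CPM in ΔNFκB mice, a difference of 1.81 ± 0.17 (adjusted p 0.00361). Thbs1 went from 59.7 ± 11.8 to 384 ± 0.47 CPM in WT mice and from 85.1 ± 4.07 to 35.5 ± 2.76 CPM in ΔNFκB mice, a difference of -3.94 ± 0.21 (adjusted p 0.000397). In the fibroblast list 0 of 27 members were higher and 17 lower (0 and 21 adjusted over the list alone). The fibroblast list had adjusted p 3.47e-10 by camera and adjusted p = 0.608 with an estimated correlation. Among goblet cell genes 15 of 18 members were higher and 0 lower (16 and 0 adjusted over the list alone). The goblet cell list had adjusted p 5.96e-12 by camera and adjusted p = 0.286 with an estimated correlation. Among nerve and glia markers 0 of 17 members were higher and 13 lower (0 and 15 adjusted over the list alone). The nerve and glia list had adjusted p 1.73e-07 by camera and adjusted p = 0.491 with an estimated correlation. Of interferon response genes 11 of 32 members were higher and 0 lower (13 and 0 adjusted over the list alone). The interferon list had adjusted p 5.88e-07 by camera and adjusted p = 0.626 with an estimated correlation. Of mitochondrial genes 14 of 20 members were higher and 0 lower (18 and 0 adjusted over the list alone). The mitochondrial list had adjusted p 3.47e-10 by camera and adjusted p = 0.594 with an estimated correlation. Of endothelial markers 0 of 12 members were higher and 8 lower (0 and 11 adjusted over the list alone). The endothelial list had adjusted p 1.38e-05 by camera and adjusted p = 0.608 with an estimated correlation. Of neutrophil markers 0 of 17 members were higher and 7 lower (0 and 9 adjusted over the list alone). The neutrophil list had adjusted p 0.00129 by camera and adjusted p = 0.594 with an estimated correlation. Among absorptive colonocyte genes 6 of 24 members were higher and 2 lower (8 and 2 adjusted over the list alone). The colonocyte list had adjusted p 0.00567 by camera and adjusted p = 0.626 with an estimated correlation. Among fatty acid oxidation genes 6 of 18 members were higher and 1 lower (7 and 1 adjusted over the list alone). The fatty acid list had adjusted p 0.0122 by camera and adjusted p = 0.626 with an estimated correlation.

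Another 4 lists with fewer members past the test were lower in the difference. Among NF-κB response genes 0 of 27 members were higher and 5 lower (0 and 5 adjusted over the list alone). The NF-κB response list had adjusted p 0.0389 by camera and adjusted p = 0.626 with an estimated correlation. Among monocyte and macrophage markers 0 of 21 members were higher and 4 lower (0 and 5 adjusted over the list alone). The macrophage list had adjusted p 0.0452 by camera and adjusted p = 0.68 with an estimated correlation. Among smooth muscle markers 0 of 14 members were higher and 2 lower (0 and 2 adjusted over the list alone). The smooth muscle list had adjusted p 0.0122 by camera and adjusted p = 0.705 with an estimated correlation. The B and plasma cell list had 0 of 18 members past either test. Its adjusted p was 0.0122 by camera and 0.705 with an estimated correlation. The NF-κB call ended without WT untreated replicate 1 (0.476), ΔNFκB untreated replicate 1 (0.0644) and ΔNFκB DSS replicate 1 (0.0874) and with a sex term (0.424), in a range of 0.00442 to 0.476; with that term 3 members were higher and 3 lower. The monocyte and macrophage call ended without WT untreated replicate 2 (0.30), WT DSS replicate 2 (0.082), ΔNFκB untreated replicate 1 (0.10) and ΔNFκB DSS replicate 1 (0.0805), in a range of 0.00699 to 0.30. The smooth muscle call ended without WT untreated replicate 2 (0.183) and WT DSS replicate 1 (0.0724), in a range of 2.73e-07 to 0.183, and with a sex term 11 of its members were lower. The B cell call ended without WT untreated replicate 1 (0.0836), ΔNFκB untreated replicate 1 (0.152) and ΔNFκB DSS replicate 2 (0.332) and with a sex term (0.0809), in a range of 0.00060 to 0.332. The p38 list did not pass, with 1 of 23 members higher and 3 lower (adjusted p 0.447). Tnf stood at 0.75 ± 0.89, Il1b at -1.50 ± 1.09, Rela at -0.14 ± 0.17, Ppm1d at -0.44 ± 0.24 and Mapk14 at -0.0 ± 0.17 (adjusted p 0.579, 0.355, 0.592, 0.229 and 0.997), and Il6, with 0.257 ± 0.219 CPM in ΔNFκB DSS and 0 counts in ΔNFκB untreated mice, had adjusted p 0.928, so none of them passed.

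Among the smallest p-values for a higher response in ΔNFκB mice were those of Ccl6 at 2.12 ± 0.14, Nox1 at 3.68 ± 0.26, Gal3st2c at 2.45 ± 0.18, the mucin Muc4 at 2.88 ± 0.23 and Fgfbp1 at 2.47 ± 0.20 (adjusted p 0.00138, 0.00171, 0.00176, 0.00218 and 0.00218). Those for a lower response belonged to Thbs1, the integrin Itgb8 at -5.0 ± 0.34, Hmcn2 at -2.68 ± 0.21, Nbl1 at -2.56 ± 0.22, Spaca6 at -2.78 ± 0.24 and Abcc9 at -2.97 ± 0.26 (adjusted p 0.00138, 0.00218, 0.00268, 0.00268 and 0.00284). In all 3102 responses differed, 1513 higher and 1589 lower in ΔNFκB mice, 2140 by at least 2-fold. The split depended on scaling (1202 and 1743 with upper quartile, 1580 and 1564 with RLE factors). Of the 3102, 2015 had fitted values of opposite sign (at most 337 called so in both genotypes). The change was larger in ΔNFκB mice for 1766 and smaller for 1336. The number was 1553 without WT untreated replicate 2, 1490 without WT DSS replicate 1, 792 without WT DSS replicate 2, 933 without ΔNFκB untreated replicate 1, 1555 without ΔNFκB DSS replicate 1 and 489 without ΔNFκB DSS replicate 2. Of 49 called values of named genes 27 kept their call with each library left out in turn and 22 lost it without at least 1.

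**Figure D3:**
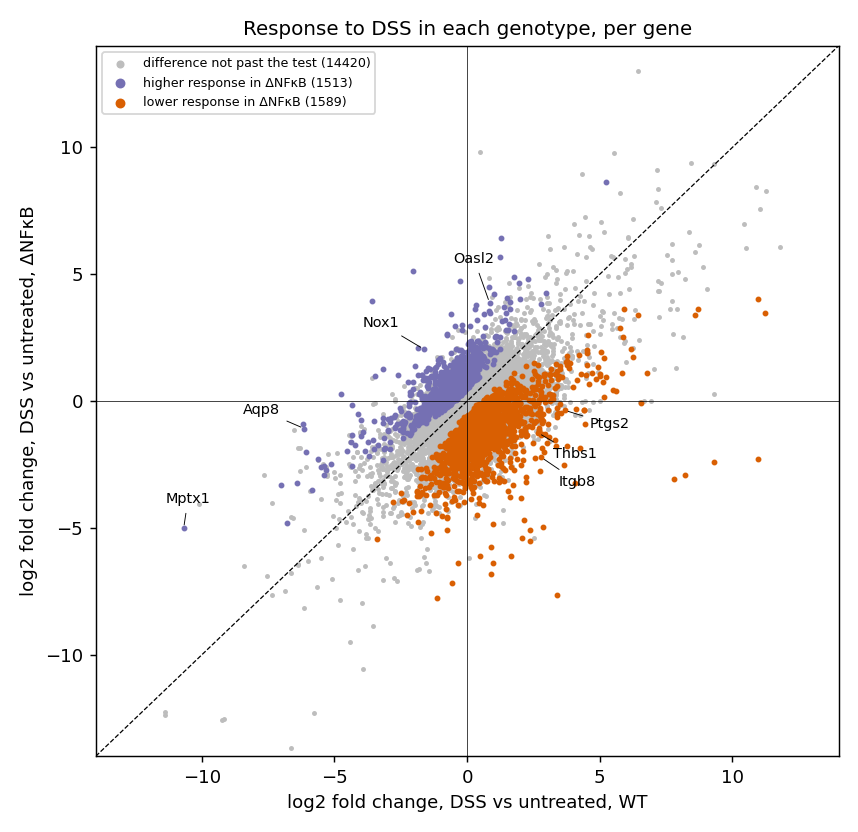
Log2 fold change with DSS in WT mice (horizontal axis) against that in ΔNFκB mice (vertical axis), 1 point per tested gene, with the dashed line at equal responses. Purple points are the 1513 genes with a higher and orange points the 1589 with a lower response in ΔNFκB mice.

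The responses of the 2 genotypes overlapped. DSS raised 1133 genes in both genotypes, where 488 would be shared if the calls were independent, and lowered 1463 in both, against 633. Of 2933 genes called in both, 337 went in opposite directions. Across all tested genes the 2 sets of log2 fold changes correlated at r = 0.543; genes are not independent replicates. Genes called in WT mice had a median change of 0.98 in WT and, in the direction of the WT change, 0.45 in ΔNFκB mice. Genes called in ΔNFκB mice had a median of 1.07 there and 0.43 in WT mice. Each median is inflated in the genotype that made the calls. The value of 0.45 ran from 0.39 to 0.68 with single libraries left out, and was 0.52 with DESeq2 and 0.74 with a sex term.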

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

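Tests of explanations for the first 2 patterns below, and their bounds, were chosen after the results were seen; only that for male accessory gland transcripts was written before its result. The values in the next paragraphs stand out because the DSS response differed between genotypes, as log2 ΔNFκB minus WT by the genotype by treatment test, with n = 2 mice per group.

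The responses of 3102 genes differed. Among those with the largest statistical support were Ccl6 (2.12), Nox1 (3.68), Gal3st2c (2.45), Muc4 (2.88) and Fgfbp1 (2.47) above WT, and Thbs1 (-3.94), Itgb8 (-5.0), Hmcn2 (-2.68), Nbl1 (-2.56), Spaca6 (-2.78) and Abcc9 (-2.97) below it. Within lists, differences past the test with each library left out in turn were those of Aqp8 (5.06), Top2a (1.81), Kif11 (1.73), Mki67 (1.64), Uchl1 (-3.17), Stmn2 (-2.61), Tubb3 (-3.15), Col18a1 (-2.83), Agr2 (2.17), Klk1 (2.36), Gcnt3 (1.97), Oasl2 (3.02), Mmp9 (-2.52) and Ptgs2 (-4.05). List medians past both camera and fry were those of cell cycle genes (1.66), goblet cell genes (1.73), mitochondrial genes (0.72) and nerve and glia markers (-2.18); none passed camera with an estimated correlation (0.286, 0.286, 0.594 and 0.491).

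Other differences within lists passed with all libraries and lost their adjusted p under 0.05 when 1 was left out. Car1 stood at -1.52 and lost the call without WT DSS replicate 2 (0.0518) and ΔNFκB DSS replicate 2 (0.0672), in a range of 1.31e-06 to 0.0672. Vil1 stood at 1.21 and lost it without WT DSS replicate 2 (0.0744), ΔNFκB untreated replicate 1 (0.0637) and ΔNFκB DSS replicate 2 (0.0741), in a range of 4.18e-05 to 0.0744. Tie1 (-2.47) lost it without ΔNFκB DSS replicate 2 (0.0666), in a range of 0.000684 to 0.0666. Tek (-2.0) lost it without ΔNFκB DSS replicate 2 (0.0554), in a range of 0.00154 to 0.0554. Cdh5 (-2.94) lost it without WT DSS replicate 2 (0.0508), ΔNFκB untreated replicate 1 (0.0504) and ΔNFκB DSS replicate 2 (0.064), in a range of 2.07e-05 to 0.064. Pparg (1.35) lost it without WT DSS replicate 2 (0.0527) and ΔNFκB DSS replicate 2 (0.0632), in a range of 0.000384 to 0.0632. Cpt2 (0.91) lost it without WT DSS replicate 2 (0.0675) and ΔNFκB DSS replicate 2 (0.0778), in a range of 0.0048 to 0.0778. Zbp1 (3.21) lost it without ΔNFκB DSS replicate 2 (0.0509), in a range of 1.43e-09 to 0.0509. Isg15 (3.46) lost it without WT DSS replicate 2 (0.0509), in a range of 2.58e-05 to 0.0509. Ndufa9 (0.86) lost it without ΔNFκB DSS replicate 2 (0.0574), in a range of 0.00241 to 0.0574. Cox5a (0.86) lost it without WT DSS replicate 2 (0.0514), ΔNFκB untreated replicate 1 (0.0523) and ΔNFκB DSS replicate 2 (0.0666), in a range of 0.00107 to 0.0666. Uqcrfs1 (0.84) lost it without WT DSS replicate 2 (0.0623), ΔNFκB untreated replicate 1 (0.0548) and ΔNFκB DSS replicate 2 (0.0679), in a range of 0.00171 to 0.0679.

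Immune and muscle genes followed the same course. Arg1 (-5.65) lost its call without ΔNFκB untreated replicate 1 (0.0738) and ΔNFκB DSS replicate 2 (0.0565), in a range of 0.000207 to 0.0738. Clec4d (-3.15) lost it without WT DSS replicate 2 (0.051) and ΔNFκB untreated replicate 2 (0.0593), in a range of 0.00431 to 0.0593. Chil3 (-5.21) lost it without WT untreated replicate 2 (0.0724), WT DSS replicate 1 (0.056), WT DSS replicate 2 (0.0809), ΔNFκB untreated replicate 1 (0.566), ΔNFκB DSS replicate 1 (0.0657) and ΔNFκB DSS replicate 2 (0.0872) and with DESeq2 (0.0703) and limma-voom (0.0746), in a range of 0.000634 to 0.566. Marco (-11.14) lost it without WT untreated replicate 1 (0.051), WT untreated replicate 2 (0.0869), WT DSS replicate 2 (0.0891), ΔNFκB untreated replicate 1 (0.973), ΔNFκB DSS replicate 1 (0.0784) and ΔNFκB DSS replicate 2 (0.114) and with limma-voom (0.266), in a range of 0.000316 to 0.973. Ngp (-13.26) lost it without WT DSS replicate 2 (0.0636), ΔNFκB untreated replicate 1 (1), ΔNFκB DSS replicate 1 (0.0604) and ΔNFκB DSS replicate 2 (0.0773) and with limma-voom (0.0659), in a range of 4.43e-05 to 1. The values of Marco and Ngp depend on the prior count, since Ngp had 0 counts in both WT untreated libraries and Marco 0.0399 CPM. Without ΔNFκB untreated replicate 1 the differences were -2.17 for Chil3, -3.39 for Marco and -5.55 for Ngp, and without WT untreated replicate 1 -9.15 for Arg1 and -9.09 for Chil3. Relb (-0.96) lost its call without WT DSS replicate 1 (0.0505) and ΔNFκB DSS replicate 2 (0.0723), in a range of 0.00901 to 0.0723. Traf1 (-2.07) lost it without WT untreated replicate 1 (0.0504), WT untreated replicate 2 (0.0977), WT DSS replicate 1 (0.109), WT DSS replicate 2 (0.0741), ΔNFκB untreated replicate 1 (0.109), ΔNFκB DSS replicate 1 (0.0544) and ΔNFκB DSS replicate 2 (0.131), in a range of 0.00397 to 0.131. Lmod1 (-1.45) lost it without ΔNFκB DSS replicate 1 (0.0571), in a range of 0.0013 to 0.0571. Kcnmb1 (-1.32) lost it without WT untreated replicate 2 (0.0813), WT DSS replicate 1 (0.0835), WT DSS replicate 2 (0.135), ΔNFκB untreated replicate 1 (0.113), ΔNFκB untreated replicate 2 (0.0786), ΔNFκB DSS replicate 1 (0.132) and ΔNFκB DSS replicate 2 (0.0946) and with DESeq2 (0.0527), limma-voom (0.0529) and a replicate block (0.0566), in a range of 0.0127 to 0.135.

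The first pattern is the number of differing responses. A sex term left 3772 genes past the test (3102 without it, 2711 shared). It rests on 2 WT untreated mice, so it cannot tell sex from other differences between them. With RLE and upper quartile factors the lower count was 2945. Whether a single library carries it cannot be told apart at 2 mice per group. As given above, the count fell when any of several libraries was left out. A sex difference without DSS, a scaling error shared by all factors, and litter or cage stay open. So do the severity or timing of disease in single mice and, for rises and falls alike, the mix of tissues in each sample. An effect of the altered locus was not separated from these.

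The second pattern is the lower level of nerve, vessel and fibroblast markers in ΔNFκB mice after DSS. Less muscle wall in those samples cannot be told apart. Nerve and glia minus smooth muscle markers (list mean log2 CPM, ± SE over mice) differed from WT DSS mice by -1.91 ± 0.429, against the explanation. From ΔNFκB untreated mice it changed by 0.46 ± 0.187, so smooth muscle markers fell at least as far there. They also fell in WT mice, where nerve markers did not. With upper quartile factors the highest of the 3 list medians was -1.97. Sex is argued against by Y-linked transcripts of at most 0.209 CPM in the DSS libraries. A scaling error shared by all factors and how far each mouse had recovered stay open as untested. An effect of the altered locus was not separated from these.

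The third pattern is the set of male accessory gland transcripts in ΔNFκB untreated replicate 1, where Tgm4 had 4394 counts, against 23 in WT untreated replicate 2 and at most 1 elsewhere. Prostate tissue beside the colon in that sample may be the source: of the other markers on the list with enough counts, 4 of 5 were more than 4 times higher there than in each other library. Among them were Pbsn (1363 counts), 9530002B09Rik (284) and Msmb (18), whereas Ceacam10, which every library expressed, had 187 there and 42 to 314 elsewhere. Seminal vesicle genes of the Svs family had 0 or 1 counts in every library. No biological explanation was tested.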

How the results depend on the processing

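The sex term was chosen after the data were seen, and the other alternatives before; the cause of each change below was not tested, except that a left-out library also removes a mouse. The number of genes called moved by more than 1.5 times for the untreated genotypes with DESeq2 (264), no filter (330), a sex term (176), a replicate block (0) and only the 2 groups compared (0), and for DSS in ΔNFκB mice with a sex term (3343). Replicate numbers do not pair the mice, since deviations correlated at -0.126 to 0.244 between groups. The median response in ΔNFκB mice of genes called in WT was 0.52 with DESeq2 and 0.74 with a sex term. With single libraries left out, the numbers ran from 3298 to 6228 for DSS in WT, 3373 to 6548 for DSS in ΔNFκB, 0 to 200 for untreated genotypes, 484 to 3781 after DSS and 489 to 3669 for the difference, and the median response from 0.39 to 0.68. Other alternatives kept counts within 1.5 times. With a sex term, 3960 genes (62.7%) of those called for DSS in WT, 2935 (47.3%) for DSS in ΔNFκB, 53 (77.9%) for untreated genotypes, 3427 (97.9%) after DSS and 2711 (87.4%) in the difference were called in the same direction.

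Of 284 gene values, 284 kept direction and side of the threshold with upper quartile factors, with the count minimum of CPM and with the Ensembl table, 283 of 283 without receptor and ribosomal genes, 282 with RLE factors, 269 with no filter, 267 with DESeq2, 263 with a replicate block, 262 with limma-voom, 261 with a sex term and 204 of 219 with only the 2 groups compared. With single libraries left out 2003 values kept both, 245 lost the threshold, 8 gained it and 15 changed sign. Of 226 called values, 154 kept their call with each library left out in turn and 72 lost it without at least 1. Of list calls with libraries left out, 495 kept, 31 were lost and 2 changed sign: T and NK markers with DSS in ΔNFκB (adjusted p 0.792 without ΔNFκB untreated replicate 2, lowest 1.53e-06) and smooth muscle markers in untreated mice (0.0231 without WT untreated replicate 2, lowest 3.44e-10).

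Signs changed as follows (log2, with ranges over left-out libraries in brackets). For DSS in ΔNFκB with a sex term: Xist -0.17, Uty 0.067, Ddx3y 0.039, Ppm1d 0.0097. For untreated genotypes without WT untreated replicate 2: Myh11 -0.015 (to 0.73), Gm16685 0.19 (from -2.24), Tnf 1.26 (from -1.31) and Il1b 0.12 (from -1.51). Without ΔNFκB untreated replicate 2: Rela -0.011 (to 0.15). After DSS: Gm16685 0.40 without WT DSS replicate 2 and 0.072 without ΔNFκB DSS replicate 1 (from -0.66), Rela 0.040 without WT DSS replicate 1 (from -0.0931), and Tnf -0.26 without ΔNFκB DSS replicate 2 (to 0.53). In the difference without WT untreated replicate 2: Gm16685 -0.47 (to 1.96) and Tnf -1.11 (to 1.46). Mapk14, whose difference was near 0, stood at 0.014 with RLE factors, 0.014 with DESeq2, 0.0076 with limma-voom, 0.027 with no filter, 0.0061 with a replicate block, 0.012 with a sex term, and 0.0019, 0.082, 0.15 and 0.020 (from -0.16) without WT untreated 1, WT DSS 1, ΔNFκB untreated 1 and ΔNFκB DSS 2. Of these, Xist, Uty and Ddx3y were called with all libraries.

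The share of calls that were higher went with upper quartile factors from 47.9% to 51.1% for DSS in WT, 45.7% to 40.5% for DSS in ΔNFκB, 41.6% to 32.6% after DSS and 48.8% to 40.8% in the difference. These factors put the median of all genes in the difference at -0.14, against -0.05 with TMM, and no median of a list called by camera changed sign with RLE or upper quartile factors. That of the p38 list, with DSS in ΔNFκB mice, did with RLE factors (0.011, against -0.011). Depth limits genes near the floor of 0.177 to 0.325 CPM per library, where only bounds are given.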

Other observations

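Of 65 replication-dependent histone genes, a group chosen after its values were seen and not tested as a list, 21 passed the test as lower in untreated ΔNFκB than in untreated WT mice and 0 as higher, with a median log2 fold change of -0.89. No gene of that comparison, and so none of these, passed when any 1 of 5 libraries was left out, with a replicate block or with only the 2 groups compared. After DSS the median of these genes between genotypes was 0.10. There were 2 mice per group.

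Mettl7a2 and Mettl7a3, adjacent paralogs also singled out after their values were seen, had 0 counts in both untreated ΔNFκB mice. Untreated WT mice had 43 and 54 counts of Mettl7a2 and 36 and 40 of Mettl7a3. After DSS, WT mice had 4 and 2 counts of Mettl7a2 and 11 and 3 of Mettl7a3, and ΔNFκB mice 2 and 1 of Mettl7a2 and 2 and 5 of Mettl7a3. Of the exon bases of Mettl7a2, 28.2% lie in exons of other genes, so its counts are uncertain.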
